A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

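Total RNA of 4 lines of Saccharomyces cerevisiae was measured at 4 times on Agilent single-colour yeast arrays, 1 array per line and time. Per the labels' protocols, RNA was labelled with Cy3 by the standard Agilent procedure, and no extraction protocol is given. Per the file headers, the slides were read with Agilent Feature Extraction 10.7.1.1, which gives an intensity for each spot after subtracting background and removing trends across the array, not scaled between arrays, and also the raw median intensity of the spot and of its local background. The deposited value table holds log2 values of 16 arrays and 6107 of the 6256 probes, each probe centred on its median over the 8 arrays of a slide, as the values show. It therefore holds no difference between slides, and no value from it is given for a comparison that crosses slides. Within a slide its differences between arrays had a correlation of 0.998 or more with those computed here.

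The main values are the log2 of the processed intensity, averaged over a probe's 2 spots (without a spot marked non-uniform where the other was not), minus the array's 75th percentile. A probe entered if it lay well above background on at least 3 of 16 arrays, which left 6165 of 6227 genes. The brightest probe stood for the 28 genes with several probes. The files name genes, and 5740 systematic names matched the RefSeq gene table, which is of another genome assembly than the one in the file headers and served for names only, so no positions are given. GPP1 and GPP2 also go by the names RHR2 and HOR2.

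All comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Changes with time were fitted on all 16 arrays with a term for the line. Differences between lines after removal were fitted on the 12 arrays at 45, 90 and 150 min with a term for the time. Differences at 0 min, and the mean of the later times minus 0 min in a line minus the same in another, came from a fit to all arrays with terms for time, line and line by later time. The 34 gene lists, markers of mating type, meiosis and plasmids among them, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. No call of a list held with an estimated correlation in any comparison. Correlations across genes are Pearson's r and Spearman's rho. What line differences that share the vec arrays have in common was simulated 100 times without any effect.

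The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names HOG1 and MET3 throughout, GPD1, GPP1, GPP2, STL1, HSP12, CTT1 and GRE2 in comparisons with vec, the 10 highest and 10 lowest genes with a symbol that passed the test and moved the same way at every time or in every line, and up to 4 members per list. Its use at 0 min, for the change from 0 min and for the osmostress genes in comparisons of HOG1 lines was added after the values were seen. A gene well above background on no array of a side is given as a bound, and so are the differences of STL1 that use line WT at 45 min, its value there raised to the lowest well above background on that array. The fits were tested on simulated arrays with 200 changed genes of 6165. In H minus vec after removal 59.4%, 85.9% and 98.5% of changes of 0.5, 1 and 2 log2 units were recovered. In WT minus vec at 0 min the shares were 4.48%, 62.1% and 91.0%, and in the change from 0 min of H minus WT they were 4.62%, 35.9% and 83.1%. The alternatives changed the background correction (normexp, on the median spot intensity since the files hold no mean), the scaling (median, quantile), the filter, the probes per gene, the variance model, the threshold, the terms of the fit, the values used and the lines, times or slide in the fit. No replicate numbers pair the arrays, and groups of 1 array allow no test for outlying arrays within a group.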

Results

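The expression of yeast genes was measured on 16 single-colour microarrays of Saccharomyces cerevisiae total RNA. The arrays fall into 4 lines of cells, each sampled at 0, 45, 90 and 150 min after methionine was taken away, with 1 array per line and time. Per the series record, 3 lines carry a HOG1 gene behind the MET3 promoter, which methionine shuts off and its removal switches on, in cells without their own HOG1, and the other line (vec) carries an empty plasmid. Hog1 is the mitogen-activated protein kinase of the response to high osmolarity, and the series title names intrinsically active HOG1 as its subject. Line WT carries the wild-type gene. The labels of the remaining lines conflict: line H is called HOG1 D170A in one label field and H in another, and line 170 is called HOG1 D170A+F318L in one field and D170A in another, so no mutation is assigned to either line here. The signal at the 75th percentile of an array ran from 4926 to 11306 units, and 93.4% to 98.8% of the spots lay well above background. Lines WT and H shared 1 slide of 8 arrays, and vec and line 170 shared the other. Values below are log2 differences with the standard error of limma's fit. No line and time was repeated, so errors and p-values measure how steady a difference was over the 3 times after removal, or over the 4 lines for a change with time, and not how much cultures vary. The small number of arrays limits the precision.

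The introduced gene came first, as a check of the labels. HOG1 (YLR113W) stood at 1.89, 1.65 and 1.51 log2 units relative to the array's 75th percentile in lines WT, H and 170 at 0 min, and at 5.64, 5.55 and 6.12 at 45 min. In vec it stood at -1.67, -2.32, -2.11 and -2.15 over the 4 times. After removal HOG1 was higher than in vec by 7.81 ± 0.093 in line WT, by 7.65 ± 0.093 in line H and by 8.29 ± 0.093 in line 170 (limma, largest adjusted p = 2.7e-10, at 3 of 3 times each). Before removal it was already higher than in vec, by 3.57 ± 0.16, 3.32 ± 0.16 and 3.18 ± 0.16. HOG1 was higher in line 170 than in line WT by 0.47 ± 0.093 (adjusted p = 0.014), and H minus 170 was -0.63 ± 0.093 (adjusted p = 0.0062). Both cross slides, and HOG1 no longer passed in 5 of 13 alternatives for 170 minus WT, with values down to 0.13, and in 4 of 13 for H minus 170, with values up to -0.078. H minus WT was -0.16 ± 0.093 (adjusted p = 0.29). MET3 (YJR010W), the ATP sulfurylase gene whose promoter drives the constructs, rose by 5.18 ± 0.27 over the 4 lines. Its difference from vec was -0.26 ± 0.42, 0.02 ± 0.42 and 0.25 ± 0.42 in lines WT, H and 170, none past the threshold. In WT minus vec MET3 passed in 1 of 13 alternatives, without 45 min (-1.03). These means do not show equal induction: MET3 in WT minus vec was 1.27, -1.43 and -0.64 at 45, 90 and 150 min, and at 45 min MET3 stood at 1.43 in vec and at 2.71, 2.66 and 2.65 in WT, H and 170. The HOG1 spots lay well above background on all 4 vec arrays, at percentile 32.7 to 39.3 of the genes of the array. Neither the part of HOG1 removed from the genome nor the place of the probe in it is given, so the vec signal does not settle whether the labels hold, while the rise in the other lines goes with them.

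**Figure D1:**
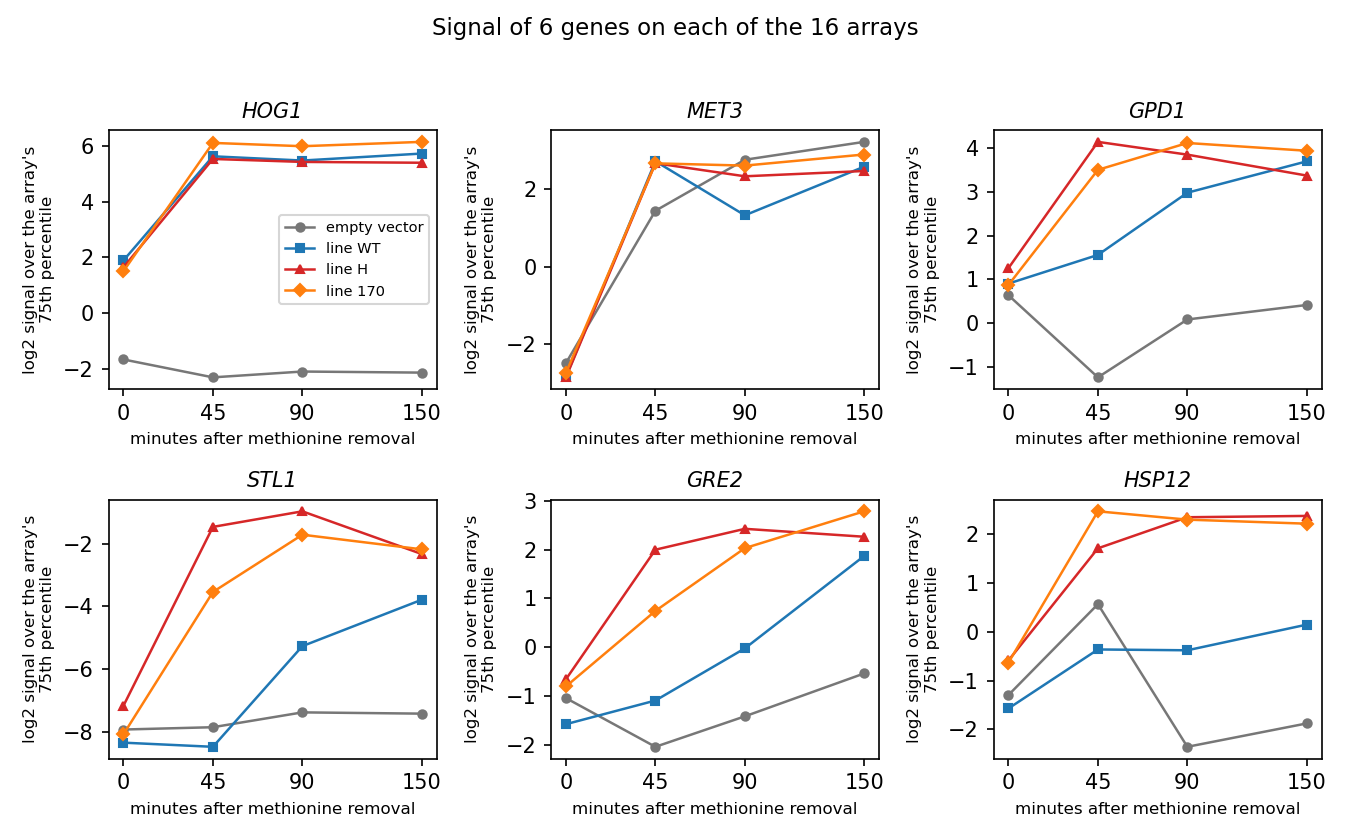
Each panel plots the log2 signal of a gene relative to the array's 75th percentile (y axis) against minutes after methionine removal (x axis), with 1 point per array and 1 line of points per line of cells. HOG1 stood at 5.64 or 5.55 in lines WT and H and at 6.12 in line 170 at 45 min, against -2.32 in the empty vector, and GRE2 stood at -1.09 in line WT against 2.0 in line H at that time.

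The first comparison asks what changed after methionine removal in all 4 lines together. No array came from a culture kept in methionine. These changes can therefore also hold elapsed time and handling of the cultures, and induced HOG1 in lines WT, H and 170. Genes of sulfur uptake and methionine synthesis were among those that rose most over the mean of the later times: MET3 (5.18 ± 0.27), MET14 (4.99 ± 0.24), MET32 (4.91 ± 0.28) and SUL2 (4.20 ± 0.34), which encode ATP sulfurylase, adenylylsulfate kinase, a regulator of the pathway and a sulfate permease, and MMP1 (4.09 ± 0.32), an S-methylmethionine permease gene. The cell wall genes CWP1 (5.39 ± 0.39), CIS3 (4.33 ± 0.52) and TOS6 (4.60 ± 0.43), the acid phosphatase gene PHO3 (4.16 ± 0.45) and the S-phase cyclin gene CLB6 (4.64 ± 0.34) rose as well. CLB6 was not well above background at 0 min in lines WT, H and 170, and its value ran from 2.33 to 5.21 under the alternatives. The high-affinity glucose transporter genes HXT6 (-4.72 ± 0.24) and HXT7 (-4.63 ± 0.24) fell most, followed by ATG41 (-4.22 ± 0.35), SRL4 (-4.19 ± 0.11) and ARO5 (-4.10 ± 0.18), by RGI1 (-3.93 ± 0.38), BIO5 (-3.90 ± 0.22) and RSB1 (-3.90 ± 0.23) and by FMP23 (-3.87 ± 0.094) and ADH5 (-3.87 ± 0.26). Each of these genes moved the same way in 4 of 4 lines. In vec CIS3, TOS6 and PHO3 rose by 1.29, 2.29 and 1.67, against 4.86, 5.37 and 4.95 in line WT. MET3 rose by 4.94 in vec and 5.02 in WT, and MMP1 by 5.18 and 4.48. At 45 min 4704 of 6165 genes passed the test (1963 higher, 2741 lower), at 90 min 4614 (2078 and 2536) and at 150 min 4534 (2071 and 2463), of which 2089, 1978 and 1785 differed at least 2-fold (limma). Time goes with the place of an array on its slide, and on the slide of vec and line 170 alone the counts were 2879, 2707 and 2510. At 150 min 45.7% of the called genes were higher, but 50.7% with median scaling and 50.8% with quantile normalization. The median gene changed by -0.17 at 45 min, and by -0.02 with median scaling and -0.04 with quantile normalization.

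Genes that make ribosomes and drive cell cycle entry rose with time, and genes of stress, stored carbohydrate, respiration, amino acid synthesis and autophagy fell. The counts are at 45 min, and the values of single genes are over the mean of the later times. 136 of 137 ribosomal protein genes were higher and 1 lower (the same adjusted over the list alone), with camera adjusted p = 1.2e-35 and adjusted p = 0.52 with an estimated correlation. RPL9A (3.55 ± 0.25) and RPS22B (3.28 ± 0.21) were among them. 69 of 70 ribosome biogenesis genes were higher and 1 not called (the same adjusted over the list alone), with camera adjusted p = 7.3e-27 and adjusted p = 0.52 with an estimated correlation. HAS1 (3.39 ± 0.18) and NOP1 (2.77 ± 0.14) were among them. 19 of 30 methionine and sulfur genes were higher, 2 lower and 9 not called (the same adjusted over the list alone), with camera adjusted p = 4.7e-04 and adjusted p = 0.81 with an estimated correlation. 24 of 25 G1/S genes were higher and 1 not called (the same adjusted over the list alone), with camera adjusted p = 4.0e-08 and adjusted p = 0.52 with an estimated correlation. RNR1 (3.78 ± 0.20), PCL1 (3.40 ± 0.43) and POL30 (2.94 ± 0.14) were among them. 16 of 29 cell wall genes were higher, 1 lower and 12 not called (the same adjusted over the list alone), with camera adjusted p = 0.01 and adjusted p = 0.81 with an estimated correlation. CWP2 (2.82 ± 0.40) and ECM33 (2.40 ± 0.24) were among them. The cell wall list's median did not rise in vec, where it stood at 1.64, 1.63, 1.52 and 1.60 at 0, 45, 90 and 150 min, against 0.87, 2.07, 1.93 and 2.37 in WT, 0.86, 2.40, 2.79 and 2.84 in H and 0.34, 2.12, 2.53 and 2.69 in 170. 1 of 44 general stress genes was higher, 41 lower and 2 not called (the same adjusted over the list alone), with camera adjusted p = 2.3e-07 and adjusted p = 0.52 with an estimated correlation. PHM8 (-3.36 ± 0.12), CYC7 (-3.34 ± 0.24) and HSP78 (-2.81 ± 0.20) were among them. 19 of 21 trehalose and glycogen genes were lower and 2 not called (the same adjusted over the list alone), with camera adjusted p = 1.9e-05 and adjusted p = 0.52 with an estimated correlation. GLG1 (-3.07 ± 0.16) and TSL1 (-2.52 ± 0.24) were among them. 1 of 42 respiration and TCA cycle genes was higher, 33 lower and 8 not called (the same adjusted over the list alone), with camera adjusted p = 9.8e-04 and adjusted p = 0.81 with an estimated correlation. QCR9 (-2.35 ± 0.15) and CYT1 (-2.23 ± 0.22) were among them. 4 of 36 amino acid genes under Gcn4 were higher, 27 lower and 5 not called (the same adjusted over the list alone), with camera adjusted p = 0.0038 and adjusted p = 0.81 with an estimated correlation. HIS4 (-3.77 ± 0.33) and ARG3 (-3.51 ± 0.21) were among them. 1 of 16 autophagy genes was higher, 14 lower and 1 not called (the same adjusted over the list alone), with camera adjusted p = 9.8e-04 and adjusted p = 0.52 with an estimated correlation. ATG1 (-2.11 ± 0.078) and ATG8 (-1.46 ± 0.16) were among them. 3 of 20 glucose-repressed genes were higher, 15 lower and 2 not called (the same adjusted over the list alone), with camera adjusted p = 0.042 and adjusted p = 0.55 with an estimated correlation. JEN1 (-2.92 ± 0.22) fell, while ADH2 (3.36 ± 0.47) rose. At 90 and 150 min each of these lists, over the 4 lines together, moved the same way as at 45 min, with camera adjusted p of at most 0.0066 and adjusted p = 0.45 to 0.74 with an estimated correlation. For glycolysis and fermentation the median was 0.25 at 45 min and -0.38 with quantile normalization, so no direction is given.

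The next comparisons set each HOG1 line against the empty vector over 45, 90 and 150 min, to see what the introduced gene does once induced. In line WT, GPD1 (3.0 ± 0.45), the glycerol-3-phosphate dehydrogenase gene of glycerol synthesis, was 8.01-fold higher than in vec, and GPP2 (1.26 ± 0.35), a glycerol-phosphate phosphatase gene, and GRE2 (1.58 ± 0.41) and RTC3 (2.65 ± 0.70) were higher too. PIR3 (3.69 ± 0.31), a cell wall gene, PRM10 (2.11 ± 0.45) of the cell wall integrity response and KDX1 (2.68 ± 0.36), whose product resembles the kinase of that response, were higher with them, as were the drug transporter gene QDR2 (2.99 ± 0.26), SHH3 (2.78 ± 0.28) and SPO75 (2.58 ± 0.20) and the serine deaminase gene CHA1 (2.57 ± 0.20). HO (-2.38 ± 0.33), the endonuclease gene of mating-type switching, and the flavohemoglobin gene YHB1 (-2.27 ± 0.24) were lowest, with ARO10 (-1.92 ± 0.21) and ARO9 (-1.86 ± 0.16) of aromatic amino acid breakdown, the daughter-cell genes CTS1 (-1.80 ± 0.23), DSE1 (-1.76 ± 0.28) and DSE2 (-1.75 ± 0.26), and PRM9 (-1.81 ± 0.20), FUS1 (-1.64 ± 0.13) and DAN1 (-1.55 ± 0.29). STL1 (a mean of at most 1.85), HSP12 (1.02 ± 0.59), CTT1 (0.40 ± 0.20) and GPP1 (0.05 ± 0.26) did not pass the test, though STL1 and HSP12 passed in 1 alternative each, and STL1 and DAN1 were not well above background in line WT at 45 min. RTC3 and GPP2 no longer passed in 5 of 13 alternatives, GRE2 in 3 and GPD1 in 2, and RTC3 was 0.92, 2.49 and 4.53 at 45, 90 and 150 min and 1.71 without 150 min. In this comparison 1829 of 6165 genes passed the test, 1039 higher and 790 lower, and 226 differed at least 2-fold (limma), and each gene named here as higher or lower differed the same way at 3 of 3 times, as did those named in the next 5 comparisons of lines. The share of called genes that were higher was 56.8%, but 48.0% with normexp, 49.8% with median scaling and 47.7% with quantile normalization, so no direction is given for the whole. WT and vec lie on different slides. Without the arrays at 90 min 193 genes passed, 23 of the 35 named in the text that had passed among them, and without those at 150 min 1093. 187 of the 1829 genes were called the same way in the change from 0 min. Measured as the change from 0 min, the difference had the opposite sign for AGA2, BAR1, CHA1, CTS1, DAN1, DSE1, DSE2, ENO2, FAR1, GPM1, HTB2, PGK1, PRM9 and QDR2.

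10 of 29 Hog1 osmostress targets in line WT were higher, 2 lower and 17 not called (10 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.012 and adjusted p = 0.63 with an estimated correlation. 17 of 29 cell wall genes were higher, 2 lower and 10 not called (18 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.0019 and adjusted p = 0.63 with an estimated correlation. YPS3 (1.81 ± 0.19) and CWP1 (1.55 ± 0.36) were among them. 17 of 22 ergosterol synthesis genes were lower and 5 not called (19 lower adjusted over the list alone), with camera adjusted p = 3.1e-10 and adjusted p = 0.41 with an estimated correlation. HMG1 (-1.22 ± 0.17) and ERG3 (-1.10 ± 0.11) were among them. 1 of 17 glycolysis genes was higher, 15 lower and 1 not called (1 higher and 16 lower adjusted over the list alone), with camera adjusted p = 6.1e-08 and adjusted p = 0.57 with an estimated correlation. PGK1 (-1.19 ± 0.21), GPM1 (-1.16 ± 0.16) and ENO2 (-1.07 ± 0.20) were among them. 8 of 9 histone genes were lower and 1 not called (9 lower adjusted over the list alone), with camera adjusted p = 7.8e-06 and adjusted p = 0.57 with an estimated correlation. HTB2 (-1.07 ± 0.17) and HHF1 (-0.85 ± 0.12) were among them. 2 of 26 pheromone response genes were higher, 14 lower and 10 not called (2 higher and 15 lower adjusted over the list alone), with camera adjusted p = 1.2e-06 and adjusted p = 0.44 with an estimated correlation. AGA2 (-1.53 ± 0.18), BAR1 (-1.5 ± 0.10) and FAR1 (-1.41 ± 0.15) were among them. 6 of 7 a-mating-type-specific genes were lower and 1 not called (the same adjusted over the list alone), with camera adjusted p = 3.1e-06 and adjusted p = 0.44 with an estimated correlation. The medians of the ergosterol, glycolysis, histone, pheromone and a-specific lists against vec were -0.55, -0.51, -0.38, -1.26 and -1.60 at 0 min already, and 644 of the 1829 genes (35.2%) were called the same way at 0 min.

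In line H the same comparison gave larger differences from vec. STL1 (5.97 ± 0.81), the glycerol importer gene, was 62.5-fold higher (4.30 log2 units with normexp background correction), and RTC3 (5.15 ± 0.70), GPD1 (4.05 ± 0.45), GRE2 (3.57 ± 0.41), HSP12 (3.36 ± 0.59) and GPP2 (2.52 ± 0.35) were higher as well, as was the cytosolic catalase gene CTT1 (1.15 ± 0.20). PIR3 (5.65 ± 0.31), KDX1 (4.34 ± 0.36) and PRM10 (3.84 ± 0.45), SHH3 (4.46 ± 0.28), PNS1 (3.91 ± 0.32) and QDR2 (3.77 ± 0.26) followed. The lowest were YHB1 (-2.68 ± 0.24) and HO (-2.67 ± 0.33), then the daughter-cell genes DSE2 (-2.66 ± 0.26) and DSE1 (-2.60 ± 0.28) and CTS1 (-2.36 ± 0.23), DSE4 (-2.31 ± 0.32) and SCW11 (-2.24 ± 0.26), and PRM9 (-2.41 ± 0.20), TIP1 (-2.32 ± 0.44) and BUD9 (-2.21 ± 0.26). GPP1 (-0.06 ± 0.26) did not pass the test. In this comparison 3070 of 6165 genes passed the test, 1554 higher and 1516 lower, and 606 differed at least 2-fold (limma). The share that was higher was 50.6%, but 42.0% with normexp, 47.0% with median scaling and 43.8% with quantile normalization. H and vec lie on different slides. Without the arrays at 90 min 1324 genes passed, 42 of the 43 named in the text that had passed among them. 738 of the 3070 genes were called the same way in the change from 0 min. Measured as the change from 0 min, the difference had the opposite sign for BAR1, BUD9, CLN1, CLN2, CTS1, DSE1, DSE2, ENO2, FAR1, HTB2, QDR2, RPL7A, SCW11, SPI1 and TIP1.

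21 of 29 Hog1 osmostress targets in line H were higher, 1 lower and 7 not called (23 higher and 1 lower adjusted over the list alone), with camera adjusted p = 3.5e-07 and adjusted p = 0.41 with an estimated correlation. The list's median was 1.31, against 0.47 in line WT and 0.33 in line H at 0 min. 23 of 44 general stress genes were higher, 3 lower and 18 not called (24 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.0018 and adjusted p = 0.73 with an estimated correlation. DDR2 (3.20 ± 0.47), ALD3 (2.63 ± 0.27) and SPI1 (1.75 ± 0.37) were among them. 21 of 29 cell wall genes were higher, 7 lower and 1 not called (the same adjusted over the list alone), with camera adjusted p = 4.5e-04 and adjusted p = 0.47 with an estimated correlation. YPS3 (2.61 ± 0.19) and PST1 (2.38 ± 0.30) were among them. 20 of 25 G1/S genes were lower and 5 not called (21 lower adjusted over the list alone), with camera adjusted p = 6.3e-06 and adjusted p = 0.53 with an estimated correlation. CLN2 (-1.63 ± 0.22) and CLN1 (-1.53 ± 0.19) were among them. 2 of 19 M/G1 and daughter-cell genes were higher, 13 lower and 4 not called (4 higher and 13 lower adjusted over the list alone), with camera adjusted p = 0.0041 and adjusted p = 0.73 with an estimated correlation. 9 of 9 histone genes were lower (the same adjusted over the list alone), with camera adjusted p = 1.0e-05 and adjusted p = 0.44 with an estimated correlation. HTB2 (-1.81 ± 0.17) was among them. 16 of 17 glycolysis genes were lower and 1 not called (the same adjusted over the list alone), with camera adjusted p = 1.5e-07 and adjusted p = 0.44 with an estimated correlation. PGK1 (-1.71 ± 0.21) and ENO2 (-1.62 ± 0.20) were among them. 18 of 22 ergosterol genes were lower and 4 not called (20 lower adjusted over the list alone), with camera adjusted p = 1.5e-07 and adjusted p = 0.41 with an estimated correlation. ERG3 (-1.52 ± 0.11) was among them. 119 of 137 ribosomal protein genes were lower and 18 not called (126 lower adjusted over the list alone), with camera adjusted p = 1.7e-19 and adjusted p = 0.51 with an estimated correlation. RPL7A (-0.84 ± 0.10) was among them. 4 of 26 pheromone response genes were higher, 19 lower and 3 not called (the same adjusted over the list alone), with camera adjusted p = 2.5e-05 and adjusted p = 0.44 with an estimated correlation. BAR1 (-2.09 ± 0.10), FAR1 (-1.98 ± 0.15) and FUS1 (-1.93 ± 0.13) were lower and AFR1 (2.18 ± 0.19) was higher. The medians of the general stress, G1/S, M/G1, histone, glycolysis, ergosterol, ribosomal protein and pheromone lists against vec were already 0.51, -0.85, -1.39, -0.53, -0.89, -0.63, -1.07 and -1.63 at 0 min, and 1177 of the 3070 genes (38.3%) were called the same way then.

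Line 170 shares its slide with vec, so this difference does not cross slides. RTC3 (5.42 ± 0.70), STL1 (5.07 ± 0.81) and GPD1 (4.11 ± 0.45) were higher than in vec, GPD1 by 17.3-fold, with HSP12 (3.55 ± 0.59), GRE2 (3.19 ± 0.41) and GPP2 (2.08 ± 0.35) and CTT1 (1.09 ± 0.20). STL1 was 3.53 in its lowest alternative and no longer passed in 2 of 13. The cell wall gene PIR3 (4.96 ± 0.31), KDX1 (4.08 ± 0.36), SHH3 (3.41 ± 0.28) and PNS1 (3.32 ± 0.32) were higher too. YHB1 (-3.29 ± 0.24) and HO (-2.94 ± 0.33) were lowest, with BAR1 (-2.67 ± 0.10), the protease gene that ends the response to alpha factor, the meiotic gene NDJ1 (-2.62 ± 0.12), CYB5 (-2.33 ± 0.12) of cytochrome b5, the daughter-cell genes DSE1 (-2.45 ± 0.28), SCW11 (-2.34 ± 0.26) and DSE4 (-2.23 ± 0.32), and SEO1 (-2.43 ± 0.55). GPP1 (0.35 ± 0.26) did not pass the test, but did in 1 of 14 alternatives. In this comparison 2003 of 6165 genes passed the test, 989 higher and 1014 lower, and 405 differed at least 2-fold (limma). Without the arrays at 90 min 577 genes passed, 29 of the 35 named in the text that had passed among them, and without those at 150 min 1107 passed. 598 of the 2003 genes were called the same way in the change from 0 min. Measured as the change from 0 min, the difference had the opposite sign for BAR1, CLB1, CLB2, CLN1, DSE1, FAR1, MFA1, PGK1, SCW11 and YOX1.

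23 of 29 Hog1 osmostress targets in line 170 were higher, 1 lower and 5 not called (24 higher and 1 lower adjusted over the list alone), with camera adjusted p = 5.7e-10 and adjusted p = 0.2 with an estimated correlation, and the list's median was 1.35. 15 of 44 general stress genes were higher, 3 lower and 26 not called (17 higher and 3 lower adjusted over the list alone), with camera adjusted p = 2.0e-04 and adjusted p = 0.59 with an estimated correlation. DDR2 (2.61 ± 0.47) and ALD3 (2.41 ± 0.27) were among them. 18 of 29 cell wall genes were higher, 7 lower and 4 not called (19 higher and 7 lower adjusted over the list alone), with camera adjusted p = 1.7e-05 and adjusted p = 0.38 with an estimated correlation. PRM10 (3.19 ± 0.45), CWP1 (2.78 ± 0.36) and YPS3 (2.24 ± 0.19) were among them. 23 of 25 G1/S genes were lower and 2 not called (24 lower adjusted over the list alone), with camera adjusted p = 1.1e-09 and adjusted p = 0.38 with an estimated correlation. CLN1 (-1.71 ± 0.19) and YOX1 (-1.66 ± 0.28) were among them. 12 of 16 G2/M genes were lower and 4 not called (14 lower adjusted over the list alone), with camera adjusted p = 1.7e-06 and adjusted p = 0.38 with an estimated correlation. CLB1 (-1.65 ± 0.20) and CLB2 (-1.42 ± 0.19) were among them. 9 of 9 histone genes were lower (the same adjusted over the list alone), with camera adjusted p = 2.5e-07 and adjusted p = 0.38 with an estimated correlation. 18 of 22 ergosterol genes were lower and 4 not called (20 lower adjusted over the list alone), with camera adjusted p = 3.4e-10 and adjusted p = 0.2 with an estimated correlation. ERG5 (-1.72 ± 0.13) and ERG3 (-1.64 ± 0.11) were among them. 12 of 17 glycolysis genes were lower and 5 not called (1 higher and 12 lower adjusted over the list alone), with camera adjusted p = 1.3e-04 and adjusted p = 0.51 with an estimated correlation. PGK1 (-1.16 ± 0.21) was among them. 1 of 26 pheromone response genes was higher, 22 lower and 3 not called (the same adjusted over the list alone), with camera adjusted p = 1.3e-09 and adjusted p = 0.2 with an estimated correlation. MFA1 (-1.92 ± 0.16) and FAR1 (-1.84 ± 0.15) were among them. 7 of 7 a-mating-type-specific genes were lower (the same adjusted over the list alone), with camera adjusted p = 3.7e-07 and adjusted p = 0.26 with an estimated correlation. At 0 min the medians of the general stress, G1/S, G2/M, histone, ergosterol, glycolysis, pheromone and a-specific lists were already 0.70, -0.98, -1.52, -0.18, -0.97, -1.07, -1.96 and -2.77, and 707 of the 2003 genes (35.3%) were called the same way.

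The differences from vec went together across genes, which are not independent replicates. Pearson's r was 0.895 (covariance 0.343, 870 genes higher and 762 lower in both against 249 and 249 for independent lists) for lines H and 170, 0.897 (covariance 0.271, 925 genes higher and 720 lower in both against 262 and 194 for independent lists) for lines WT and H, and 0.792 (covariance 0.202, 632 genes higher and 432 lower in both against 167 and 130 for independent lists) for lines WT and 170. Lines without any effect that share the vec arrays gave r of 0.497 to 0.503 and a covariance of 0.0151 to 0.0153 in 100 simulations. The observed covariances of 0.202 to 0.343 were larger, so scatter of the shared arrays accounts for only a small part of them. The simulation held no difference of the vec culture itself, which would enter each of these comparisons. At 0 min limma called 1503, 1990 and 1892 genes in WT, H and 170 minus vec. Part of the excess can therefore come from the vec culture, and this was not tested. The calls of all lines also use the same estimate of each gene's spread. More genes than for independent lists can thus be called in both without a common effect.

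**Figure D2:**
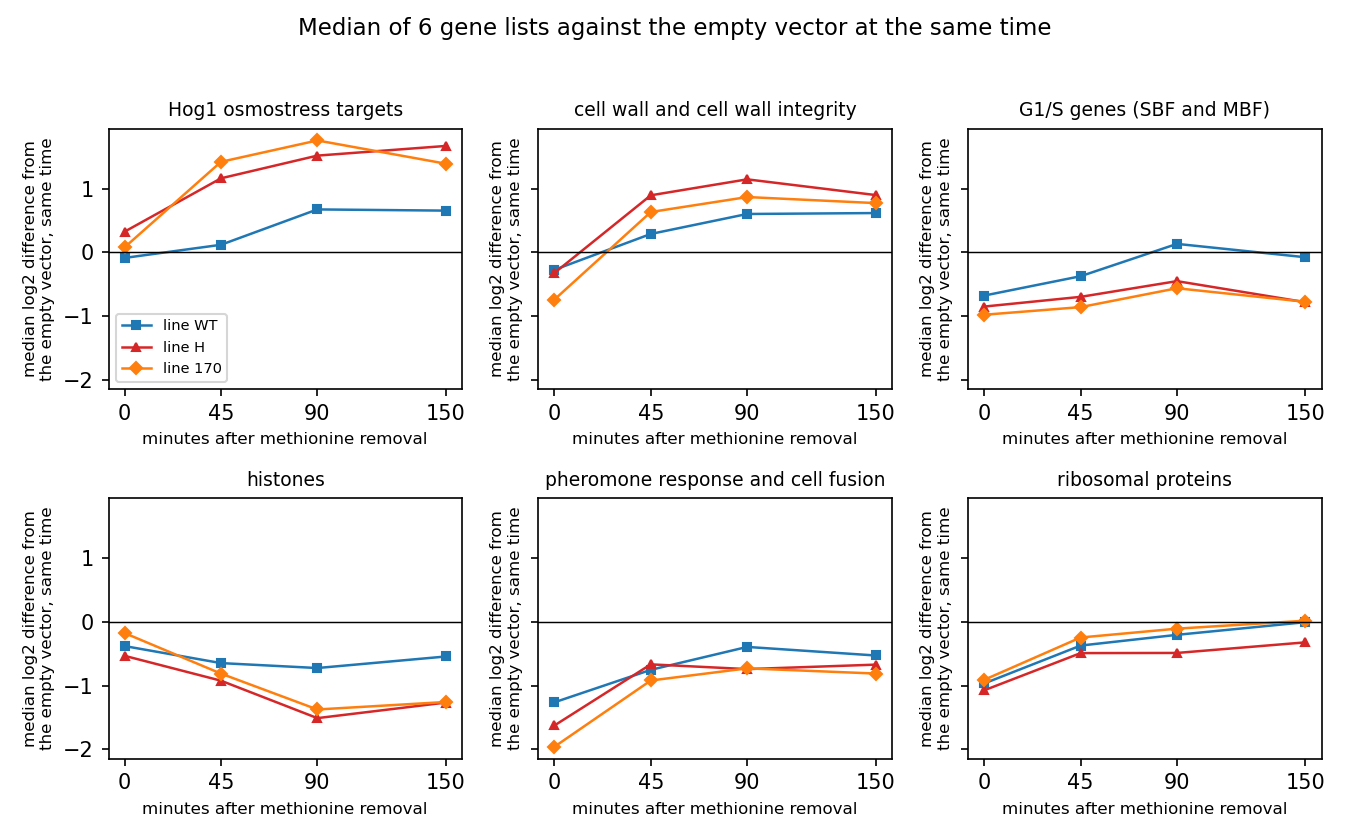
Each panel plots the median over a gene list of the log2 difference from the empty vector at the same time (y axis) against minutes after methionine removal (x axis), with 1 point per array of lines WT, H and 170. At 45 min the median of the Hog1 osmostress targets was 0.12 in line WT, 1.16 in line H and 1.42 in line 170.

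Lines H and WT lie on the same slide, and this comparison asks how the HOG1 version of line H differs from the wild-type one. STL1 (a mean of at least 4.11) was higher in line H, as were NFG1 (3.54 ± 0.40), AFB1 (2.47 ± 0.41), the stress gene DDR2 (2.08 ± 0.47), GRE2 (1.98 ± 0.41), PIR3 (1.96 ± 0.31), PNS1 (1.88 ± 0.32), ARI1 (1.69 ± 0.35), HAL1 (1.69 ± 0.29), a gene of salt tolerance, and SHH3 (1.69 ± 0.28). The lowest were the G1/S genes TOS4 (-0.91 ± 0.19), CLN1 (-0.89 ± 0.19), RNR1 (-0.81 ± 0.16) and MCD1 (-0.80 ± 0.14), LYS2 (-0.84 ± 0.15) of lysine synthesis, the citrate carrier gene CTP1 (-0.84 ± 0.15), ATO3 (-0.80 ± 0.073) and PEX21 (-0.79 ± 0.11), AIM20 (-0.82 ± 0.16) and NDJ1 (-0.81 ± 0.12). STL1 was not well above background in line WT at 45 min, so its difference was at least 6.58 then, with 4.30 at 90 min, 1.46 at 150 min and 2.88 without 45 min. GPD1 (1.05 ± 0.45), GPP2 (1.26 ± 0.35) and HSP12 (2.34 ± 0.59) did not pass the test, though HSP12 passed in 6 of 14 alternatives (lowest adjusted p = 0.0043). Means hide a change over time: at 45, 90 and 150 min GPD1 was 2.59, 0.87 and -0.32, GPP2 2.38, 1.40 and 0.01 and GRE2 3.09, 2.45 and 0.40. In this comparison 384 of 6165 genes passed the test, 281 higher and 103 lower, and 70 differed at least 2-fold, all 70 of them higher (limma). At 0 min 1 gene was called in H minus WT, YDR274C, named after its value was seen, with 276 at an unadjusted p under 0.05, and limma called 0 without 90 min and 0 without 150 min (124 and 260 at an unadjusted p under 0.05). In the change from 0 min limma called 0, with 321 at an unadjusted p under 0.05. The count rests on the times: without 90 min 0 genes passed by limma (527 at an unadjusted p under 0.05), without 150 min 6, without 45 min 966, and 0 of the 27 genes named in the text that had passed did so without 90 min. With normexp background correction 61.3% of 511 called genes were higher, against 73.2%.

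9 of 29 Hog1 osmostress targets were higher and 20 not called (22 higher adjusted over the list alone), with camera adjusted p = 1.9e-12 and adjusted p = 0.19 with an estimated correlation. 8 of 44 general stress genes were higher and 36 not called (19 higher adjusted over the list alone), with camera adjusted p = 5.2e-12 and adjusted p = 0.39 with an estimated correlation. ALD3 (1.54 ± 0.27) and DDR48 (1.26 ± 0.20) were among them. 7 of 29 cell wall genes were higher and 22 not called (16 higher and 3 lower adjusted over the list alone), with camera adjusted p = 2.0e-04 and adjusted p = 0.39 with an estimated correlation. 4 of 21 trehalose and glycogen genes were higher and 17 not called (9 higher adjusted over the list alone), with camera adjusted p = 3.5e-06 and adjusted p = 0.39 with an estimated correlation. GAC1 (1.40 ± 0.27) and NTH1 (0.76 ± 0.17) were among them. 11 of 25 G1/S genes were lower and 14 not called (20 lower adjusted over the list alone), with camera adjusted p = 6.7e-11 and adjusted p = 0.39 with an estimated correlation. 5 of 9 histone genes were lower and 4 not called (8 lower adjusted over the list alone), with camera adjusted p = 2.5e-05 and adjusted p = 0.39 with an estimated correlation. HTB2 (-0.75 ± 0.17) and HHF2 (-0.67 ± 0.14) were among them.

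Line 170 differed from line WT in a comparison that crosses slides. STL1 (a mean of at least 3.22) was higher in line 170, as were NFG1 (2.85 ± 0.40), RTC3 (2.77 ± 0.70), HSP12 (2.52 ± 0.59), GRE2 (1.60 ± 0.41), DAN1 (1.55 ± 0.29), NQM1 (1.5 ± 0.21), the thiamine gene THI4 (1.45 ± 0.36), HSP32 (1.40 ± 0.17) and KDX1 (1.40 ± 0.36). AI4 (-1.58 ± 0.11), an intron-encoded gene of the mitochondrial genome, NDJ1 (-1.5 ± 0.12), the flap endonuclease gene RAD27 (-1.5 ± 0.12), DIP5 (-1.42 ± 0.31), the cyclin genes CLB6 (-1.36 ± 0.32) and CLB2 (-1.16 ± 0.19), HXT14 (-1.21 ± 0.20), POX1 (-1.18 ± 0.25) of fatty acid oxidation, PFS1 (-1.18 ± 0.22) and BAR1 (-1.17 ± 0.10) were lowest. With line WT not well above background at 45 min, STL1 differed by at least 4.50 then, by 3.55 at 90 min and 1.61 at 150 min, and by 2.58 without 45 min. The lowest value of STL1 under the alternatives was 2.57. HXT14, AI4 and PFS1 were well above background on 1, 2 and 2 of 3 arrays of line 170, and DAN1 on 2 of 3 of line WT. With the dim values raised to the lowest well above background on those arrays, their means were -0.77, -1.58, -0.93 and 1.53. CTT1 (0.69 ± 0.20) was higher, and GPD1 (1.11 ± 0.45) and GPP2 (0.83 ± 0.35) did not pass the test, at 1.95, 1.14 and 0.24 for GPD1 and 1.25, 1.26 and -0.03 for GPP2 at 45, 90 and 150 min. In this comparison 1096 of 6165 genes passed the test, 424 higher and 672 lower, and 81 differed at least 2-fold (limma). In the change from 0 min limma called 0 genes, with 490 at an unadjusted p under 0.05. Without 90 min 0 genes passed by limma (861 at an unadjusted p under 0.05) and without 150 min 34, and with normexp background correction 51.4% of 1367 called genes were higher, against 38.7%. Measured as the change from 0 min, the difference had the opposite sign for AI4, BAR1, NDJ1 and SWI5.

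13 of 29 Hog1 osmostress targets were higher and 16 not called (16 higher adjusted over the list alone), with camera adjusted p = 2.4e-09 and adjusted p = 0.37 with an estimated correlation. 13 of 44 general stress genes were higher and 31 not called (17 higher adjusted over the list alone), with camera adjusted p = 8.6e-09 and adjusted p = 0.64 with an estimated correlation. HSP26 (1.35 ± 0.25) and ALD3 (1.32 ± 0.27) were among them. 18 of 25 G1/S genes were lower and 7 not called (22 lower adjusted over the list alone), with camera adjusted p = 5.8e-10 and adjusted p = 0.64 with an estimated correlation. CLN1 (-1.07 ± 0.19) and PCL1 (-1.07 ± 0.26) were among them. 7 of 16 G2/M genes were lower and 9 not called (14 lower adjusted over the list alone), with camera adjusted p = 4.0e-05 and adjusted p = 0.64 with an estimated correlation. SWI5 (-1.05 ± 0.16) and HOF1 (-0.72 ± 0.18) were among them. 6 of 9 histone genes were lower and 3 not called (7 lower adjusted over the list alone), with camera adjusted p = 7.1e-04 and adjusted p = 0.64 with an estimated correlation. 13 of 70 ribosome biogenesis genes were lower and 57 not called (the same adjusted over the list alone), with camera adjusted p = 1.5e-05 and adjusted p = 0.87 with an estimated correlation. NOG1 (-0.77 ± 0.18), RRP14 (-0.73 ± 0.12) and CBF5 (-0.68 ± 0.092) were among them. The median of the ribosomal proteins was 0.07, and -0.02 with quantile normalization, so no direction is given.

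Lines H and 170 were compared with each other, again across slides. SPO75 (1.59 ± 0.20), SPO74 (at least 2.20-fold) and IME4 (1.29 ± 0.35), genes of sporulation and meiosis, AI4 (1.33 ± 0.11), the pectinase gene PGU1 (at least 1.87-fold), SIP4 (1.15 ± 0.24), a regulator of gluconeogenesis genes, HXT14 (1.13 ± 0.20), SHH3 (1.05 ± 0.28), RME1 (1.03 ± 0.17) and FRE7 (1.02 ± 0.19) were higher in line H. IME4 and HXT14 were well above background on 1 of 3 arrays of line 170. With the dim values raised to the lowest well above background on those arrays, their means were 0.91 and 0.69. IME4 no longer passed in 8 of 12 alternatives, with values from 0.061 to 1.88. Lower in line H were DAN1 (-1.0 ± 0.29), AUA1 (-0.99 ± 0.10), the mitochondrial acyl carrier gene ACP1 (-0.97 ± 0.11), the glycolysis genes ENO2 (-0.94 ± 0.20) and GPM1 (-0.91 ± 0.16), PET122 (-0.89 ± 0.11), IZH4 (-0.82 ± 0.20), URA3 (-0.81 ± 0.10), a uracil synthesis gene and common plasmid marker, HHY1 (-0.79 ± 0.22) and PRM9 (-0.79 ± 0.20). The osmostress genes STL1 (0.89 ± 0.81), GPD1 (-0.06 ± 0.45), GPP2 (0.44 ± 0.35) and GRE2 (0.38 ± 0.41) and HSP12 (-0.18 ± 0.59) and CTT1 (0.06 ± 0.20) did not pass the test. In this comparison 1013 of 6165 genes passed the test, 601 higher and 412 lower, and 34 differed at least 2-fold (limma). In the change from 0 min limma called 0 genes, with 247 at an unadjusted p under 0.05. Without 90 min 1 gene passed and without 150 min 2, and the share of called genes that were higher was 59.3%, but 38.8% with normexp, 48.8% with median scaling and 49.2% with quantile normalization. Measured as the change from 0 min, the difference had the opposite sign for AI4, FRE7 and SIP4, and so it had with normexp background correction for HXT14, PGU1 and SPO74.

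1 of 29 Hog1 osmostress targets was higher and 28 not called (the same adjusted over the list alone), the called member being CRG1 (0.87 ± 0.14), and camera gave adjusted p = 0.78. 73 of 137 ribosomal protein genes were lower and 64 not called (98 lower adjusted over the list alone), with camera adjusted p = 1.7e-30 and adjusted p = 0.8 with an estimated correlation. RPL7A (-0.77 ± 0.10) and RPL11A (-0.73 ± 0.10) were among them. 9 of 17 glycolysis genes were lower and 8 not called (12 lower adjusted over the list alone), with camera adjusted p = 2.4e-08 and adjusted p = 0.8 with an estimated correlation. TDH2 (-0.72 ± 0.14) and PDC1 (-0.65 ± 0.092) were among them.

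H minus WT and 170 minus vec share no array, and each lies within a slide. Across 6165 genes, which are not independent replicates, Pearson's r between them was 0.740 and Spearman's rho 0.666, and r was 0.754 without HOG1. At 45, 90 and 150 min taken alone r was 0.474, 0.692 and 0.651. Of the 281 genes higher in line H than in WT, 262 were among the 989 higher in line 170 than in vec, where independent lists would share 45.1, STL1, GRE2, PIR3, PNS1 and SHH3 among them. Of the 103 lower genes, 90 were among 1014, against 16.9, NDJ1 and CLN1 among them. Both sets of calls use the same estimate of each gene's spread, from a fit of all lines. They are therefore not independent, and some excess can arise without a shared effect. These differences after removal can hold what differed before induction. Across genes, the difference at 0 min had r = 0.390 with that after removal in H minus WT and r = 0.418 in 170 minus vec.

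Before induction the empty vector stood apart. At 0 min the transporter gene QDR2 (4.51 ± 0.45) and ZNF1 (3.97 ± 0.53), the glucose transporter gene HXT4 (4.01 ± 0.41), MTH1 (3.31 ± 0.53) of glucose sensing, TMA10 (4.19 ± 0.85) and the phosphate transporter gene PHO84 (3.52 ± 0.88) were higher in line H than in vec, and the inositol synthesis gene INO1 (-5.20 ± 0.72), TOS6 (-4.65 ± 0.51), the agglutinin gene AGA2 (-4.30 ± 0.31), the cyclin gene PCL1 (-4.27 ± 0.44) and the cell wall genes CIS3 (-4.24 ± 0.23), SCW10 (-3.83 ± 0.32) and UTR2 (-3.76 ± 0.26) were lower. INO1 differed from vec by -5.62 ± 0.72 in line WT and -4.89 ± 0.72 in line 170, and QDR2 by 4.08 ± 0.45 and 4.09 ± 0.45. In WT minus vec 1503 genes passed (702 higher, 801 lower), in H minus vec 1990 (894 and 1096) and in 170 minus vec 1892 (752 and 1140), against 11 in 170 minus WT and 7 in H minus 170 (limma). In line H 1 of 29 Hog1 osmostress targets was higher, 2 lower and 26 not called (1 higher adjusted over the list alone), and camera gave adjusted p = 0.33. 1 of 137 ribosomal protein genes in line H was higher, 130 lower and 6 not called (2 higher and 133 lower adjusted over the list alone), with camera adjusted p = 3.6e-38 and adjusted p = 0.65 with an estimated correlation. 30 of 42 respiration genes were higher and 12 not called (32 higher and 1 lower adjusted over the list alone), with camera adjusted p = 1.8e-08 and adjusted p = 0.65 with an estimated correlation. 1 of 26 pheromone response genes was higher, 21 lower and 4 not called (the same adjusted over the list alone), with camera adjusted p = 5.3e-11 and adjusted p = 0.42 with an estimated correlation. PRM1 (-3.85 ± 0.22) and AGA1 (-3.40 ± 0.27) were among them. On the first principal component the vec array at 0 min lay at 38.78 and the other 0 min arrays at 69.37 to 73.61. With 1 array per line at 0 min, each is assumed to vary like the later arrays. Without 90 min 418, 906 and 872 genes passed in WT, H and 170 minus vec, and 46.7%, 44.9% and 39.7% of the called genes were higher, but 51.0%, 50.1% and 50% with quantile normalization.

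**Figure D3:**
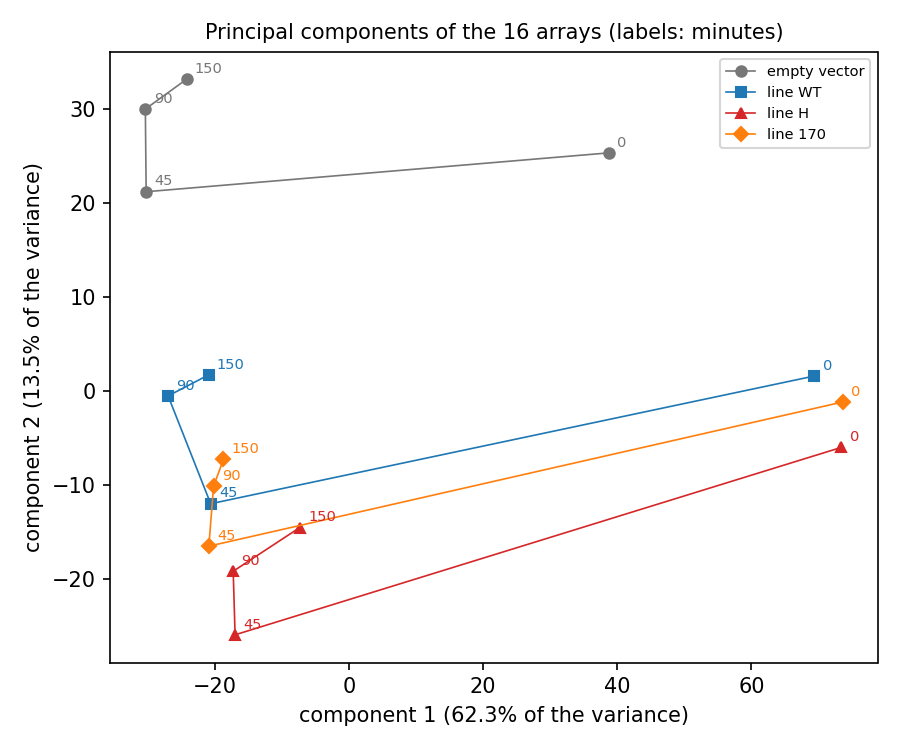
Each point is 1 of the 16 arrays, placed by the first principal component of the tested genes (x axis, 62.3% of the variance) and the second (y axis, 13.5% of the variance), with lines joining the times of a line of cells. The empty vector at 0 min lies at 38.78 on the first component, between the other arrays at 0 min, at 69.37 to 73.61, and the later arrays, which lie at -7.35 or lower.

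The change from 0 min in a HOG1 line minus the change in vec leaves out differences that were present before induction and any constant difference between slides. It also takes up what changed in vec alone. The differences for RTC3, KDX1, GPD1 and GRE2 were 5.47 ± 1.39, 4.16 ± 0.71, 3.42 ± 0.90 and 3.18 ± 0.81 in line H and 5.36 ± 1.39, 4.47 ± 0.71, 3.87 ± 0.90 and 2.95 ± 0.81 in line 170, with NFG1 (4.84 ± 0.80) and PIR3 (3.32 ± 0.63) in line H. Part of this is a fall in vec, where the mean of the later times minus 0 min was -2.48 for RTC3, -0.67 for KDX1, -0.89 for GPD1, -0.29 for GRE2 and -2.56 for PIR3, against 2.99, 3.48, 2.54, 2.89 and 0.76 in line H. In line WT their values were 3.08 ± 1.39 for RTC3, 2.65 ± 0.71 for KDX1, given there after its value was seen, 2.73 ± 0.90 for GPD1 and 2.12 ± 0.81 for GRE2. None passed the threshold (adjusted p = 0.055 for KDX1), though KDX1 did in 5 and GPD1 in 1 of 11 alternatives (lowest adjusted p = 0.03 and 0.019). STL1 did not pass in lines H and 170, at 5.21 ± 1.63 and 5.23 ± 1.63, and no value is given for line WT, where it was not well above background at 0 and 45 min. STL1 did pass in 5 of 10 alternatives in line H and 5 of 10 in line 170, with lowest adjusted p = 0.018 and 0.013. In line WT the differences were 3.57 ± 0.26 for CIS3 and 3.41 ± 0.51 for PCL1, low at 0 min, which changed by 4.86 and 4.46 against 1.29 and 1.06 in vec. For INO1 the difference of 4.37 ± 0.84 came from a change of -4.51 in vec, against -0.14 in WT. HXT4, high at 0 min, differed by -3.53 ± 0.47, -4.55 ± 0.47 and -4.78 ± 0.47 in WT, H and 170, and changed by 0.63 in vec. 7 of 29 Hog1 osmostress targets in line H were higher and 22 not called (9 higher adjusted over the list alone), with camera adjusted p = 4.7e-04 and adjusted p = 0.45 with an estimated correlation. The median level of the list was -0.32, -0.02, -0.42 and 0.43 at 0, 45, 90 and 150 min in line H, -0.63, -0.24, -0.31 and -0.44 in line 170 and -1.04, -1.98, -2.09 and -1.72 in vec. In line 170 10 of the 29 were higher and 19 not called (11 higher adjusted over the list alone), with camera adjusted p = 0.0012 and adjusted p = 0.43 with an estimated correlation. 22 of 29 cell wall genes in line 170 were higher and 7 not called (24 higher adjusted over the list alone), with camera adjusted p = 1.3e-12 and adjusted p = 0.4 with an estimated correlation. CWP2 (3.59 ± 0.24) was among them. The pheromone response genes, lower than in vec both at 0 min and later, turned the other way in this measure, as they fell further in vec: 14 of the 26 in line H were higher and 12 not called (16 higher adjusted over the list alone), with camera adjusted p = 5.1e-07 and adjusted p = 0.45 with an estimated correlation. PRM1 (3.31 ± 0.26) and AGA2 (2.62 ± 0.36) were among them, with changes of -3.49 and -2.77 in vec and -0.19 and -0.15 in line H. Limma called 516 genes in line WT (355 higher, 161 lower), 1151 in line H (738 and 413) and 1308 in line 170 (841 and 467). Without 90 min 3, 6 and 70 passed, without 150 min 71, 466 and 721, and without 45 min 906, 1875 and 1974. With quantile normalization 916, 1612 and 1616 passed, and the share that was higher went from 68.8%, 64.1% and 64.3% to 53.3%, 50.1% and 50.4%, and to 48.8% and 53.5% in lines WT and H with normexp. The median gene in 170 minus vec moved from 0.06 to -0.04 with quantile normalization.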

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

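The tests of the vector's difference at 0 min were chosen after that difference was seen. The change from 0 min differed between each HOG1 line and vec, by a test of the difference itself, in 516 genes for line WT, 1151 for line H and 1308 for line 170, with the values without each time given in the report. The change of HOG1 minus that in vec was 4.25 ± 0.19, 4.34 ± 0.19 and 5.11 ± 0.19. For GPD1 and GRE2 it was 3.42 ± 0.90 and 3.18 ± 0.81 in line H and 3.87 ± 0.90 and 2.95 ± 0.81 in line 170. In line 170 it was 1.88 ± 0.51 for GPP1 and 1.5 ± 0.40 for CTT1, which fell by less than in vec, with changes of -2.0 and -3.49. GPP1 started lower in line 170, at 2.01 against 3.54 in vec at 0 min. At 45, 90 and 150 min GPP1 stood at 5.24, 5.09 and 4.97 against 4.75, 4.85 and 4.64.

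At 0 min the vector's array stood apart from the other lines, which bears on every change from 0 min. Slide and scan do not account for it, since 170 minus vec, within a slide, called 1892 genes and 170 minus WT and H minus 170, across slides, called 11 and 7. Methionine running out early in the vector's culture does not account for it either, as the median of the methionine and sulfur genes in vec minus the other lines was -0.35, with 9 of 30 members higher in vec. Across genes, which are not independent replicates, vec minus WT at 0 min had r = 0.585 with the later change in line H, which shares no array with it. In the other such tests r was 0.541 and 0.565. At 0 min levels in WT and H had r = 0.994, and in H and 170 r = 0.991. Both differences thus subtract nearly the same levels, and r above 0 can arise without any likeness. In level, the vector's array at 0 min had r = 0.917, 0.927 and 0.938 with line H at 45, 90 and 150 min. Line WT at 0 min had 0.894, 0.895 and 0.905, so the vector's array was somewhat nearer these later arrays. The later change in line H holds elapsed time and the responses to methionine removal and to induced HOG1. So r does not single out another growth stage of the vector's culture. Another growth stage stays open as a cause. HOG1 transcript before induction, at least 3.18 log2 units above vec, cannot be told apart from another growth stage as a cause. The highest and lowest medians of the Hog1 osmostress targets at 0 min were 0.33 and -0.09, and the host of the vector is not described beyond a strain name.

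Lines H and 170 differed in 1013 genes after removal, and 1 without 90 min and 2 without 150 min. Of these genes 93.1% differed the same way in WT minus vec, which shares no array with H minus 170 but crosses the same slides, against 73.4% of all genes, so a difference between slides may account for part of them. 93.6% differed the same way at 0 min, against 72.8% of all genes, so a difference between the lines before induction may as well. A difference between the HOG1 versions stays open, as untested, because lines, slides and starting states go together.

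Of 35 splits of the 8 arrays of each time comparison, 1 gave as many genes as the real 4704, 4614 and 4534 at 45, 90 and 150 min, the real one, and the highest others gave 4, 2 and 341. The same lines are in both groups, and the 8 splits that exchange times within lines, the highest others of which gave 1, 2 and 341, are too few for a share under 0.05. The 10 splits of the 6 arrays of a comparison of lines are too few for a share under 0.05. The highest other split gave 2 genes for H minus 170, against 1013, and 0 for the comparisons of WT, H and 170 with vec and of H and 170 with WT, against 1829, 3070, 2003, 384 and 1096.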

How the results depend on the processing

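Leaving out the vector's array at 0 min was chosen after the result was seen, and it gave 4838, 4760 and 4719 genes at 45, 90 and 150 min. The correlation of line comparisons that share no array stayed between 0.691 and 0.758 under its alternatives. The HOG1 level, the mean of lines WT, H and 170 minus vec after removal, stayed between 7.86 and 7.92. Its alternatives changed only the values and the variance model. As a change from 0 min, HOG1 differed from vec by 4.25, 4.34 and 5.11 in WT, H and 170. Dimness limits few genes, as 62 of 6227 were not tested and 5796 lay well above background on all arrays. Median scaling, no filter, the mean over probes and the deposited value table, where it gives a value, left the counts of genes within 1.5 times. Of 4062 values of named genes under alternatives, 3519 kept their direction and side of the threshold, 449 no longer passed, 26 newly passed and 68 reversed. A stricter threshold lowers a count by its construction. Fewer arrays alone do not account for the drops when a time was left out. H minus WT gave 966 genes without 45 min, 0 without 90 min and 6 without 150 min, against 384 with all times. For these and the other alternatives the cause was not tested.

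At least a 2-fold difference besides the threshold left 2089, 1978 and 1785 genes at 45, 90 and 150 min, 226, 606, 405, 70, 81 and 34 in WT, H and 170 minus vec, H and 170 minus WT and H minus 170, 504, 748 and 763 in WT, H and 170 minus vec at 0 min and 256, 539 and 629 in their change. The slide of vec and 170 alone gave 2879, 2707 and 2510 at 45, 90 and 150 min. Only the arrays of the lines compared gave 835, 1904 and 938 for WT, H and 170 minus vec. Without a term for time the counts of the 6 comparisons of lines, in the order above, were 474, 1567, 694, 21, 49 and 88, and as a change from 0 min 516, 1151, 1308, 0, 0 and 0. At 0 min H minus WT gave 0 genes by limma with normexp, quantile normalization, probes well above background on all 16 arrays or an intensity trend (401, 396, 263 and 281 at an unadjusted p under 0.05). The change in WT minus vec gave 851 with normexp and 916 with quantile normalization. Calls of lists went from 137 to 0 with an estimated correlation by camera, and were 159 with fry, 126 with normexp and 127 with quantile normalization. Leaving out each time in turn gave 193 to 1492, 1324 to 3103, 577 to 2141, 0 to 966, 0 to 1413 and 1 to 938 genes in the 6 comparisons of lines, 418 to 2061, 906 to 2556, 872 to 2361 and 0 to 1 at 0 min in WT, H and 170 minus vec and H minus WT, and 3 to 906, 6 to 1875 and 70 to 1974 in the change of WT, H and 170 minus vec.

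The sign of these log2 differences turned, and the cause was not tested. Measured as the change from 0 min, the values in WT minus vec were AGA2 1.40, BAR1 0.26, CHA1 -0.10, CTS1 0.55, DAN1 0.74, DSE1 0.31, DSE2 0.37, ENO2 0.70, FAR1 1.1, GPM1 0.77, HTB2 0.82, MET3 0.080, PGK1 0.22, PRM9 0.11 and QDR2 -1.09. In H minus vec that change was BAR1 0.68, BUD9 0.25, CLN1 0.77, CLN2 1.05, CTS1 0.29, DSE1 0.53, DSE2 0.55, ENO2 1.36, FAR1 1.11, GPP1 1.29, HTB2 0.46, QDR2 -0.74, RPL7A 1.04, SCW11 1.07, SPI1 -0.084 and TIP1 1.51. In 170 minus vec that change was BAR1 1.01, CLB1 2.12, CLB2 1.77, CLN1 1.0, DSE1 0.86, FAR1 1.53, MFA1 0.86, PGK1 1.33, SCW11 1.40 and YOX1 0.94. In H minus WT that change was HOG1 0.088. In 170 minus WT that change was AI4 0.95, BAR1 0.75, NDJ1 0.50 and SWI5 0.11. In H minus 170 that change was AI4 -0.46, CTT1 -0.49, FRE7 -0.36, SIP4 -0.039 and STL1 -0.020. With normexp the values were HXT14 -0.13, PGU1 -0.14 and SPO74 -0.089 in H minus 170. With quantile normalization the values were GPP1 0.47 in H minus vec, HOG1 0.049 in H minus WT and GPD1 0.18 in H minus 170. With median scaling the value was MET3 -0.011 in H minus vec. Leaving out each time in turn gave GPP1 -0.20 to 0.27 in WT minus vec, MET3 -1.03 to 0.32 in WT minus vec, GPP1 -0.29 to 0.13 in H minus vec, MET3 -0.59 to 0.40 in H minus vec, MET3 -0.24 to 0.53 in 170 minus vec, CTT1 -0.27 to 0.31 in H minus 170, GPD1 -0.42 to 0.19 in H minus 170, GRE2 -0.063 to 0.83 in H minus 170 and HSP12 -0.35 to 0.10 in H minus 170.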

Other observations

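The tests of a difference in timing, below, were chosen after the result was seen. Genes of the Hog1 pathway itself differed from vec after removal. The list's medians in lines WT, H and 170 were already 0.30, 0.34 and 0.16 at 0 min, against 0.25, 0.35 and 0.22 after removal. The difference of the list as a whole is therefore not set down to the induced HOG1. 15 of 31 pathway components in line WT were higher, 2 lower and 14 not called (16 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.0034 and adjusted p = 0.57 with an estimated correlation. PTP2 (1.23 ± 0.12), a phosphatase gene whose product acts on Hog1, was among them. 17 of 31 components in line H were higher, 3 lower and 11 not called (the same adjusted over the list alone), with camera adjusted p = 0.0026 and adjusted p = 0.44 with an estimated correlation. PTP2 (1.89 ± 0.12), RCK1 (2.48 ± 0.10) and SMP1 (1.65 ± 0.10) were among them. For these members the difference grew after removal. They changed from 0 min by 0.44, 1.79 and -0.97 in line H, against -0.95, 0.58 and -2.24 in vec. CUP9 of the list went the other way, by -1.87 in line H against -1.04 in vec. 14 of 31 components in line 170 were higher, 4 lower and 13 not called (14 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.0019 and adjusted p = 0.38 with an estimated correlation. 2 of 21 nitrogen-repressed genes in 170 minus vec were higher, 12 lower and 7 not called (2 higher and 14 lower adjusted over the list alone), with camera adjusted p = 2.6e-04 and adjusted p = 0.51 with an estimated correlation, and the list's median was -0.61, against 0.26 at 0 min. 3 of 16 autophagy genes in H minus WT were higher and 13 not called (7 higher adjusted over the list alone), with camera adjusted p = 2.5e-05 and adjusted p = 0.39 with an estimated correlation. ATG8 (1.04 ± 0.20) was among them. 8 of 25 chaperone genes under Hsf1 in 170 minus vec were higher and 17 not called (the same adjusted over the list alone), with camera adjusted p = 2.8e-04 and adjusted p = 0.59 with an estimated correlation, and the list's median was 0.49, against 0.38 at 0 min.

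Markers of other kinds of cell were looked at as well. The alpha-mating-type list had medians of -0.27, -0.18 and -0.55 against vec in lines WT, H and 170, with camera adjusted p = 0.17, 0.6 and 0.14. The meiosis and sporulation list had 0.10, 0.26 and 0.11, with camera adjusted p = 0.5, 0.082 and 0.23. The plasmid marker list had -0.12, 0.05 and -0.11, with camera adjusted p = 0.5, 0.29 and 0.93.

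The difference of the Hog1 osmostress targets from vec might grow later in line WT than in line H. The list's medians against vec at 45, 90 and 150 min were 0.12, 0.68 and 0.66 in WT and 1.16, 1.52 and 1.67 in H. The list's level in vec fell after 0 min, so a larger difference from vec need not be a rise in the line. Neither less HOG1 transcript in WT nor a dim array accounts for the difference at 45 min, since WT minus H was 0.096 for HOG1 then, and the list's median of -0.66 in WT minus H lay at percentile 0 of random lists matched on level, whose lowest 2.5% began at -0.0643. For the list, a later divergence from vec in WT cannot be told apart from a smaller one. The slope of WT minus H was above 0 for 11 of 29 members (37.9%), with a median of -0.14 per hour. The largest slopes were above 0, as in RTC3 (2.63 ± 0.33), YJL107C (1.74 ± 0.13), GPD1 (1.64 ± 0.19) and GRE2 (1.57 ± 0.21). The measured slope of STL1 was larger, at 3.16, but STL1 was not well above background in WT at 45 min. The lowest slopes were those of RTN2 (-0.79 ± 0.17) and ALD3 (-0.57 ± 0.23). None passed limma's threshold with 3 arrays per line (lowest adjusted p = 0.07 in the list). At 150 min GPD1 stood at 3.70 in WT and 3.38 in H, GPP1 at 5.21 and 4.22 and RTC3 at 0.68 and 0.74. HSP12 stood at 0.14 and 2.37 then, and CTT1 at -2.09 and -1.14. The slope was above 0 for 22 members (75.9%) in WT minus 170 and 21 (72.4%) in WT minus vec. For the slopes of WT minus H, 170 and vec camera gave adjusted p = 0.65, 8.5e-05 and 0.01 (0.97, 0.9 and 0.87 with an estimated correlation). The smaller median difference of the list from vec in WT at all 3 times stays open as a difference between the HOG1 versions.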
